A study of Mus musculus with 4 samples.

How the data were processed

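Single-cell RNA was measured in 4 libraries from tumors grown in mice, 1 library for each host genotype (wild-type, WT, or Lrrc25-/-) and each tumor model (B16F10 melanoma, taken on day 14, or MC38 colon carcinoma, taken on day 26). Per the labels' protocols, each library pooled tumor tissue of 3 mice (100 mm3 of each tumor), and CD45+ cells isolated with magnetic beads were mixed 5:1 with the unsorted suspension before capture with the SeekOne Digital Droplet 3' kit, which attaches a cell barcode and a unique molecular identifier (UMI). The deposited values are counts, namely whole-number UMI counts per gene and barcode with no normalization. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool and the method of calling cells are not given in the sources used here. Every barcode in the matrices held at least 500 UMIs, so the sets had already been reduced to called cells.

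Gene symbols and identifiers were those of the matrices, and positions came from GENCODE M21 on GRCm38, in which 31411 of the 32285 gene identifiers had the same name. Barcodes were kept with at least 300 genes, at least 500 UMIs and at most 20% mitochondrial UMIs. Scrublet (in scanpy 1.11.5, Python 3.11.15) scored doublets in each library. Its automatic thresholds called shares that differed widely between libraries (2.26%, 0%, 20.0% and 0%), so the highest-scoring barcodes were removed at 0.5% per 1000 cells. This left 9319 cells in the WT B16F10 pool, 11543 in the Lrrc25-/- B16F10 pool, 15792 in the WT MC38 pool and 15309 in the Lrrc25-/- MC38 pool. Total UMIs before filtering were 138841749, 122558030, 105338548 and 118098009 in the same order, and the median UMIs of kept cells were 9672, 5393, 4345 and 5443.

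Cells of the libraries were normalized to a common total and log-transformed. The 2000 most variable genes, 40 principal components and 15 neighbours went into Leiden clustering at resolution 1 (igraph 0.11.9). Lrrc25, antigen receptor segments, sex-linked, ribosomal and mitochondrial genes took no part in it. Lymphoid and dendritic cells were then clustered again within each tumor model, with 30 principal components. A cluster took the name of the marker list with its highest score if at least 3 markers of that list were detected (a UMI in at least 20% of its cells and a CPM at least 1.5 times that of other lineages). It stayed unnamed where its UMI counts were low, where markers of another type were more numerous among its 10 leading genes, or where none of its own stood there with most of the list not detected. The 24 marker lists were fixed before the data were examined, and so were the classes compared, the size rule, the tests, the gene lists and the rule for named genes. The doublet share, the exclusion of clusters with over 25% doublets, the class of T cells not resolved further and the details of naming by the 10 leading genes were settled after the data had been seen. Cells left without a name made up 10.8% of the WT B16F10 pool, 14.7% of the Lrrc25-/- B16F10 pool, 33.3% of the WT MC38 pool and 31.9% of the Lrrc25-/- MC38 pool. Most of these had low UMI counts, and in MC38 a cluster led by Sox9, Tnnt2 and Crabp2 (cluster 21) held a further 2156 WT-pool and 1621 Lrrc25-/--pool cells with no listed marker among its leading genes.

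For each immune class with at least 50 cells in every library, raw UMIs were summed over cells and scaled to the class total as CPM, the usual unit of counts per 1e6 counts. Monocytes and macrophages were summed as 1 class. Within each tumor model there was 1 pool per genotype, so no test was possible there, and the spread between mice cannot be seen. A size rule was used instead, under which a gene counted as higher or lower in the Lrrc25-/- pool when it had a CPM of 20 or more in either library, a summed count of 50 or more and at least a 1.5-fold difference in CPM after a pseudocount of 1. Where the libraries of a pair differ in class total, the summed count is easier to reach for a gene high in the larger library. Fold changes are log2 values of Lrrc25-/- over WT. Intervals on counts are exact Poisson and those on shares exact binomial (Clopper-Pearson), at 95%, and these cover counting error only. For a count of 0 the upper bound of the exact interval is given. For the comparison of detection between classes, cells were thinned to 1000 UMIs.

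The only replicated test set both WT pools against both Lrrc25-/- pools, with tumor model as a second term, by quasi-likelihood F-tests in edgeR 4.0.16 (R 4.3.3) on the summed counts with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. This fit leaves 1 residual degree of freedom, and a genotype difference that is unlike in the 2 tumor models counts as error in it. Tested on simulated data with the estimated spread and 200 altered genes, the fit called 55% of genes altered 2-fold and 87% of genes altered 4-fold for monocytes and macrophages, with 4 of 14921 unaltered genes called. The corresponding values for CD8 T cells were 47%, 90% and 2 of 9952. The simulated genes had the same fold in both tumor models, with no genotype difference unlike between them. These rates hold only for such data. An exact sign test over the 2 tumor models cannot give a two-sided p below 0.5, so none is reported.

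The 25 gene lists, covering antigen presentation, interferon responses, chemokines, macrophage states, metabolism, T cell states and stress, were each summarised by the median fold of their measured members. The percentile of that median came from 10000 random lists of the same size matched on expression, and it describes genes within a pair of libraries, not mice. The genes named were, in each main class, Lrrc25, up to 8 genes each way that passed the size rule in the same direction in both tumor models, the 4 highest and 4 lowest of each model, up to 10 genes called by edgeR and up to 4 members of each list with the largest mean absolute folds. In the other classes they were up to 3 genes each way that passed in both models. Ribosomal, mitochondrial, predicted, antigen receptor, hemoglobin, Xist and Y-linked genes and markers of other cell classes were outside this ranking. Genes named beyond the rule are said to be so.

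The alternatives tried were doublets kept, a stricter cell filter (500 genes, 1000 UMIs, 10% mitochondrial UMIs), Leiden resolution 2, naming each cell by its own marker score, a pseudocount of 5, TMM scaling within each pair of libraries, no CPM minimum, means over cells of per-cell CPM, size factors of the relative log expression kind in edgeR, the Wald test of DESeq2 1.42.0, no filter on low counts and no term for tumor model. Macrophages without monocytes were added after the data had been seen. Other tools were anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, matplotlib 3.10.9 and limma 3.58.1. Random steps used seed 7.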

Results

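The series asks how loss of Lrrc25, a leucine-rich repeat membrane protein made mainly by myeloid cells, alters immunity to tumors in the host, with tumor-associated macrophages and CD8+ T cells at its centre. Single-cell transcriptomes of tumors from WT and Lrrc25-/- mice were compared in B16F10 melanoma and in MC38 colon carcinoma, with 1 library per genotype and model, each a pool of 3 mice. The libraries held 10490 barcodes and 138841749 UMIs (WT B16F10), 13036 and 122558030 (Lrrc25-/- B16F10), 18545 and 105338548 (WT MC38), and 17661 and 118098009 (Lrrc25-/- MC38). There are no replicate libraries within a model, so values from 1 model describe pools and carry counting error only.

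Lrrc25 itself was nearly absent from the myeloid cells of both Lrrc25-/- pools. In monocytes and macrophages, Lrrc25 (ENSMUSG00000049988; mm10, chromosome 8, 70616155 to 70621483, plus strand, with 2 annotated coding transcripts of 3 exons each) measured 159 CPM (155 to 164) in the WT B16F10 pool and 4.67 CPM (4.06 to 5.34) in the Lrrc25-/- pool, 34.1-fold lower. The MC38 pools measured 90.7 CPM (87.9 to 93.5) and 2.14 CPM (1.77 to 2.57), 42.4-fold lower. These levels rest on 5282, 210, 4085 and 115 UMIs. In neutrophils the level was 282 CPM (207 to 375) against 4.04 CPM (0.833 to 11.8) in B16F10, a ratio of 0.0143 (0.00285 to 0.0445) with 3 UMIs in the Lrrc25-/- pool. In MC38 it was 215 CPM against no UMI, which allows up to 8.76 CPM. A UMI of Lrrc25 was seen in 59.4% of WT B16F10 monocytes and macrophages and in 32.5% of those in MC38, against 3.91% and 1.44% in the Lrrc25-/- pools. CD8 T cells, which should lack the gene, showed a UMI in 2.5% and 1.36% of cells in the WT pools and in 0 of 751 and 0 of 745 cells in the Lrrc25-/- pools, which allows up to 0.490% and 0.494%. With monocytes and macrophages thinned to 1000 UMIs each, the shares were 14.7% and 0.518% in B16F10 and 8.27% and 0.356% in MC38. Median depths were 7583, 7644, 4758 and 6655 UMIs in monocytes and macrophages and 2958, 2283, 4566 and 4542 in CD8 T cells. The libraries are 3' tags, so the signal left does not contradict a deletion elsewhere in the gene.

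**Figure D1:**
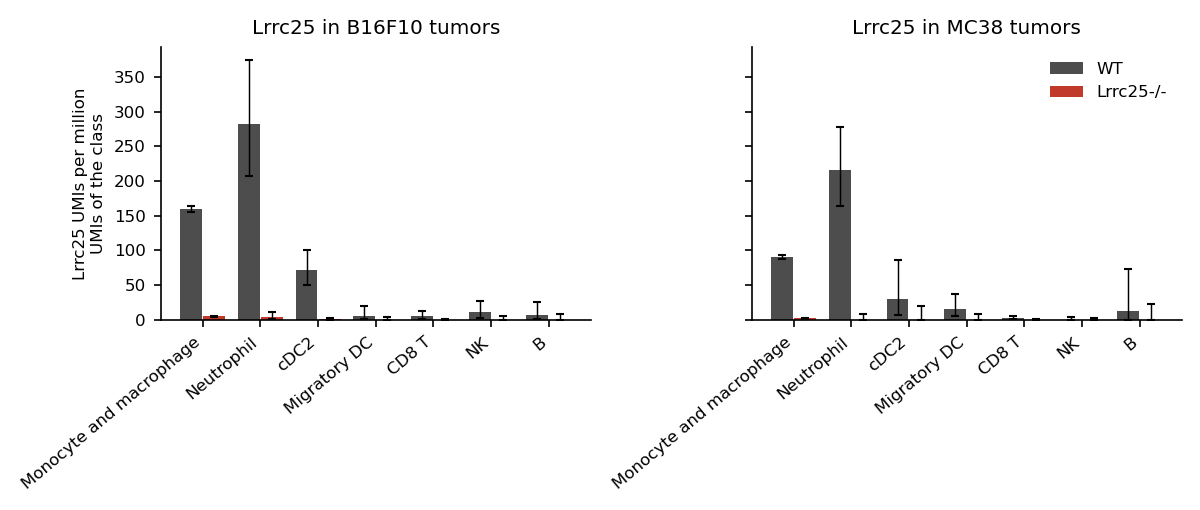
Lrrc25 level (UMIs as CPM of the class) by cell class and genotype, with 1 panel per tumor model; bars are single pools and error bars exact 95% Poisson intervals for counting error. In monocytes and macrophages it fell from 159 to 4.67 CPM in B16F10 and from 90.7 to 2.14 CPM in MC38.

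T cells made up a larger share of CD45-lineage cells in the Lrrc25-/- pool of both tumor models, and monocytes and macrophages a smaller one. In B16F10, T cells were 7.99% in the WT pool (403 of 5045 cells) and 16.8% in the Lrrc25-/- pool (1324 of 7904), a ratio of 2.10 (1.87 to 2.35). In MC38 they were 8.72% (910 of 10439) and 15.8% (1639 of 10347), a ratio of 1.82 (1.67 to 1.97). CD8 T cells were 3.96% and 9.50% in B16F10, a ratio of 2.40 (2.05 to 2.82), and 5.64% and 7.20% in MC38, a ratio of 1.28 (1.14 to 1.42). Monocytes and macrophages were 80.1% and 64.0% in B16F10 (ratio 0.799, 0.766 to 0.833) and 86.1% and 77.0% in MC38 (ratio 0.894, 0.868 to 0.922), but as a share of all cells they were 43.4% and 43.8% in B16F10 (ratio 1.01) and 56.9% and 52.0% in MC38 (0.914). These shares rest on how cells were named. With each cell named by its own marker score, the ratio for all T cells was 1.36 in B16F10 and 1.58 in MC38, that for CD8 T cells 1.59 and 1.55, and that for monocytes and macrophages in MC38 0.981. At Leiden resolution 2 the CD8 T ratio in B16F10 was 3.79.

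T cell subsets did not share 1 pattern in the 2 models. In B16F10, CD4 T cells had a ratio of 1.94 (1.44 to 2.63) and Treg cells, which restrain other T cells, one of 1.21 (0.928 to 1.57). As a share of T cells, Treg cells were 22.3% in the WT pool and 12.8% in the Lrrc25-/- pool (ratio 0.575, 0.443 to 0.751). In MC38 the Treg share of CD45-lineage cells had a ratio of 2.04 (1.64 to 2.55), while CD8 T cells went from 64.7% to 45.5% of T cells (ratio 0.702, 0.629 to 0.784). T cells that could not be assigned to a subset had ratios of 2.65 (1.87 to 3.82) in B16F10 and 3.25 (2.72 to 3.89) in MC38, so subset shares within T cells are less certain than their total. Gamma-delta T cells numbered 11 and 48 in B16F10 (ratio 2.79, 1.43 to 5.95) and 5 and 77 in MC38.

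Among other immune cells, neutrophils were 1.76% and 5.59% in B16F10 (ratio 3.17, 2.52 to 4.03) and 2.21% and 2.5% in MC38 (ratio 1.13, 0.944 to 1.36). Conventional type 2 dendritic cells had a ratio of 2.26 (1.75 to 2.97) in B16F10, which turned to 0.912 with each cell named by its own marker score, and NK cells one of 1.03 (0.834 to 1.27) in B16F10 and 1.71 (1.42 to 2.08) in MC38. Migratory dendritic cells had ratios of 1.63 (1.21 to 2.22) and 1.01 (0.721 to 1.41). Melanoma cells were 32.8% of all cells in the WT B16F10 pool and 14.6% in the Lrrc25-/- pool, but the bead-sorted and unsorted cells were mixed 5:1 before capture, a step that can itself set the balance of tumor to immune cells.

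**Figure D2:**
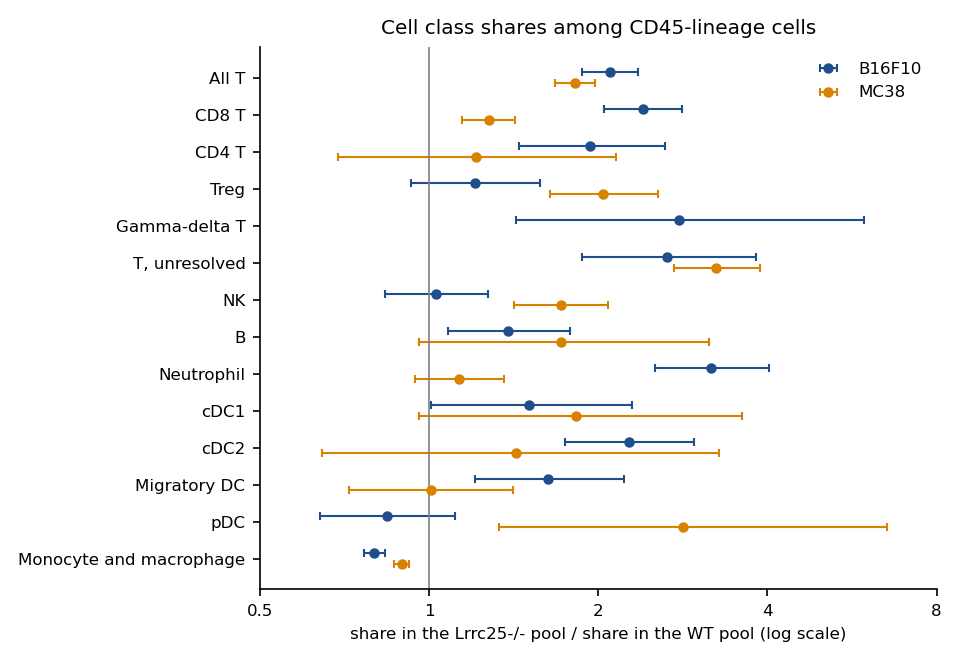
Ratio of the Lrrc25-/- to the WT share of CD45-lineage cells (log axis) for each immune class with enough cells, by tumor model, with 95% intervals for counting error. T cells lie at 2.10 in B16F10 and 1.82 in MC38, and monocytes and macrophages at 0.799 and 0.894.

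Across both tumor models, monocytes and macrophages of the Lrrc25-/- pools differed from WT ones in few genes in the same direction. Of 4192 genes measured in both models, 5 were at least 1.5-fold higher in both, where 1.32 would be if the models were independent. These were the monocyte marker Plac8, the inflammatory monocyte antigen Ly6c2, the secreted protease inhibitor Slpi, the arginine-recycling enzyme Ass1 and the interferon-induced Ifitm1. The last is a gene that the naming rule had left out as a dendritic cell marker, and it is named after its values were seen. Plac8 went from 122 to 291 CPM in B16F10 (ratio 2.38, 2.29 to 2.46) and from 98.1 to 221 CPM in MC38 (2.26, 2.18 to 2.34). Ly6c2 went from 40.7 to 83.7 CPM and from 47.6 to 108 CPM, and Slpi from 137 to 398 CPM and from 75.9 to 145 CPM. Ass1 went from 15.6 to 25.8 CPM and from 139 to 258 CPM, and Ifitm1 had log2 folds of 0.97 and 1.48. Genes lower in both were Lrrc25 and Mgl2, a lectin of alternatively activated macrophages (log2 folds -0.72 and -0.67, also a dendritic cell marker and named after its values were seen).

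In the replicated test over the 4 libraries, edgeR called 1 of 15121 genes in monocytes and macrophages, Lrrc25 (log2 fold -5.24, SE 0.188, adjusted p = 7.24e-05, lower in 2 of 2 models). In this edgeR test 563 genes, Lrrc25 included, had an unadjusted p under 0.05. They are 3.72% of those tested, below the share that this threshold passes with no difference at all. DESeq2 called 12 genes, 10 of them higher in the Lrrc25-/- pools, among them Plac8 (log2 fold 1.25, adjusted p = 2.30e-06, higher in 2 of 2 models), Slpi (1.27, 7.35e-06), Ifitm1 (1.29, 5.42e-05) and Ly6c2 (1.15, 0.000139). It also called Ctsk, a lysosomal cysteine protease, as lower (-0.96, 0.0338, lower in 2 of 2 models). Each of these 5 genes had 1 direction in both models, and their edgeR adjusted p was 0.457. Monocytes were 232 of 4043 cells of the class in the WT and 537 of 5060 in the Lrrc25-/- pool of B16F10, and 1 of 8990 and 13 of 7968 in MC38. Among macrophages alone, a choice made after the data had been seen, Plac8 had log2 folds of 1.30 and 1.16, Ly6c2 of 0.75 and 1.16, Slpi of 1.71 and 0.93 and Ass1 of 0.45 and 0.88. In MC38 this choice removed only 1 and 13 cells, so it cannot show there whether the rise lay within macrophages.

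In B16F10, monocytes and macrophages of the Lrrc25-/- pool had more RNA of inflammatory mediators, myeloid chemokines and antioxidant genes. By the size rule, 187 genes were higher and 46 lower of 4660 measured (287 and 62 with means of per-cell CPM). The median mitochondrial share of UMIs was 0.280% in WT and 0.525% in Lrrc25-/- cells of this class, against 2.54% and 2.41% in MC38. The mix of clusters in the class differed between the pools: 1 cluster held 66.0% of WT and 47.0% of Lrrc25-/- cells, another 27.4% and 40.2%. At a common mix of clusters, the share of the log2 fold left was 0.569 for Arg1, 0.569 for Ptgs2, 0.607 for Il1a and 0.630 for Cxcl3. Of 13 inflammatory activation genes 4 were higher and none lower, with a median log2 fold of 0.36, above 99.99% of random lists: Ptgs2, the inducible cyclooxygenase (85.1 to 203 CPM), the cytokines Il1a (233 to 406 CPM) and Tnf (457 to 733 CPM), and Il6 (log2 fold 0.98). Myeloid-attracting chemokines had a median of 0.37 (above 99.98%; 5 of 11 higher and 1 lower), with Cxcl3 at 714 and 1879 CPM and Cxcl1 at 1182 and 2117 CPM. Antioxidant genes had a median of 0.69 (above all random lists; 6 of 11 higher), with the cystine transporter subunit Slc7a11 at 40.3 and 104 CPM and sulfiredoxin Srxn1 at 59.0 and 122 CPM. Some genes tied to alternative activation were also higher, namely Arg1, which breaks down arginine (401 to 1027 CPM), Il10 (192 to 318 CPM) and Vegfa (31.7 to 83.9 CPM). That list as a whole had a median of 0.09 (above 89.4%; 5 of 15 higher, 2 lower).

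The highest single genes of this class in B16F10 were the platelet chemokine Ppbp (50.2 to 172 CPM), the matrix protein Thbs1 (206 to 696 CPM) and the transglutaminase Tgm2 (71.6 to 234 CPM). Plcb1, a phospholipase C (804 to 28.0 CPM), Kdm2b, a histone demethylase (65.5 to 7.91 CPM), Pgf (22.9 to 9.09 CPM) and Npl (282 to 131 CPM) were the lowest besides Lrrc25. The class also held more neutrophil marker RNA in the Lrrc25-/- pool, 137 CPM over the 8 markers against 65.6 CPM. The type I interferon response had a median of 0.29 (above 99.8%; 1 of 12 higher), with Irf7, an interferon-induced transcription factor, at 56.7 and 91.3 CPM. Proliferation genes had a median of -0.50 (below all random lists; 5 of 15 lower), with Rrm2, a ribonucleotide reductase subunit, at a log2 fold of -0.71 and Stmn1 at 411 and 266 CPM. Complement (0.21, above 98.7%), NADPH oxidase (0.29, above 99.0%), interferon-gamma-induced genes (0.19, above 94.99%), checkpoint ligands (0.19, above 95.1%), MHC class I (0.12, above 95.1%), MHC class II (0.12, above 94.4%) and phagocytic receptors (0.14, above 94.7%) had small positive medians. Oxidative phosphorylation had one of -0.20 (above 1.52%).

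In MC38, monocytes and macrophages of the Lrrc25-/- pool had more MHC and interferon-gamma-induced RNA and less RNA of lipid-handling and myeloid chemokine genes. By the size rule, 50 genes were higher and 153 lower of 5748 measured (80 and 111 with TMM scaling). Here 1 cluster held 43.4% of WT and 23.5% of Lrrc25-/- cells of the class and another 15.8% and 29.2%. MHC class II genes, which present antigen to CD4 T cells, had a median log2 fold of 0.68 (above all random lists; 4 of 7 higher), with H2-Ab1 at 1980 and 3510 CPM (ratio 1.77, 1.76 to 1.79) and the invariant chain Cd74 at 6249 and 10042 CPM. MHC class I genes had a median of 0.34 (above all random lists), with none of 15 past the size rule. Interferon-gamma-induced genes had a median of 0.47 (above all random lists; 2 of 12 higher), the 2 being the inducible nitric oxide synthase Nos2 (169 to 289 CPM) and Socs1, a brake on cytokine signalling (10.8 to 20.2 CPM). The T cell-attracting chemokine Ccl5 went from 401 to 1106 CPM (ratio 2.76, 2.71 to 2.81), Cxcl9 from 969 to 1354 CPM and Ccl3 from 137 to 86.4 CPM, in a list with a median of 0.30 (above 99.6%; 1 of 6 higher, 1 lower).

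Lipid-associated macrophage genes had a median of -0.26 in MC38 (above 0.02% of random lists; 4 of 16 lower), with Spp1, or osteopontin (2188 to 991 CPM), the fatty acid receptor Cd36 (114 to 46.9 CPM) and the lipase Lpl (30.8 to 10.2 CPM). Myeloid-attracting chemokines had a median of -0.35 (below all random lists; 3 of 10 lower, 1 higher), the 1 higher being Ccl8 (460 to 1034 CPM). Inflammatory activation (-0.16, above 2.04%) and the type I interferon response (-0.18, above 1.31%; 2 of 13 lower) had small negative medians. Alternative activation had a median of -0.02 (above 36.8%; 3 of 10 lower), with Arg1 at 2560 and 1541 CPM and Il10 at 46.8 and 20.2 CPM. At a common mix of clusters, the share of the log2 fold left was 0.799 for Spp1, 0.780 for Cd36, 0.714 for Arg1 and 0.937 for Il10. Complement had a median of 0.37 (above 99.99%; 2 of 9 higher, 2 lower), with C3 at 162 and 249 CPM. Immediate early and stress genes had one of 0.24 (above 99.98%), with Fos higher (404 to 720 CPM) and the heat shock gene Hspa1b lower (log2 fold -1.09). The highest single gene was Ly6i, a Ly6 family antigen (49.4 to 181 CPM), and the lowest besides Lrrc25 were the collagenase Mmp8 (42.8 to 7.51 CPM), Cc2d2b (24.0 to 5.06 CPM) and the growth factor Igf1 (26.7 to 7.85 CPM).

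The lists for antioxidant response (-0.07, above 18.9%), glycolysis and hypoxia (-0.03, above 22.4%), proliferation (-0.06, above 20.4%) and oxidative phosphorylation (0.10, above 91.4%) had medians near 0 in MC38. So did phagocytic receptors (0.01, above 51.5%), autophagy and lysosome (0.03, above 62.8%) and checkpoint ligands (0.03, above 62.0%). NADPH oxidase had a small positive median in MC38 (0.17, above 95.1%). With TMM scaling the antioxidant, glycolysis, proliferation and alternative activation medians of MC38 and the glycolysis median of B16F10 changed sign, so none of these carries a direction. In B16F10 the remaining lists of this class were lipid-associated genes (0.07, above 96.3%; 3 of 16 higher, among them Spp1 at 889 and 1847 CPM), glycolysis and hypoxia (0.01, above 81.3%; 4 of 18 higher), T cell-attracting chemokines (0.08, above 90.2%), autophagy and lysosome (0.03, above 83.1%) and immediate early and stress genes (0.12, above 96.9%).

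Across the 4192 genes measured in both models, 16 passed the size rule in opposite directions (3.46 if independent), and the Spearman correlation of the folds across genes was -0.15; genes are not independent replicates. Cxcl3, Ptgs2, Il1a, Arg1, Il10, Spp1 and Cd36 were higher in the Lrrc25-/- pool in B16F10 and lower in MC38. The models also differed in day of collection and, by the levels of Xist (0.0301 and 0.0222 CPM in monocytes and macrophages of the B16F10 pools, 651 and 665 CPM in those of MC38), in the sex of the hosts. The effect of model was therefore not separable from these.

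**Figure D3:**
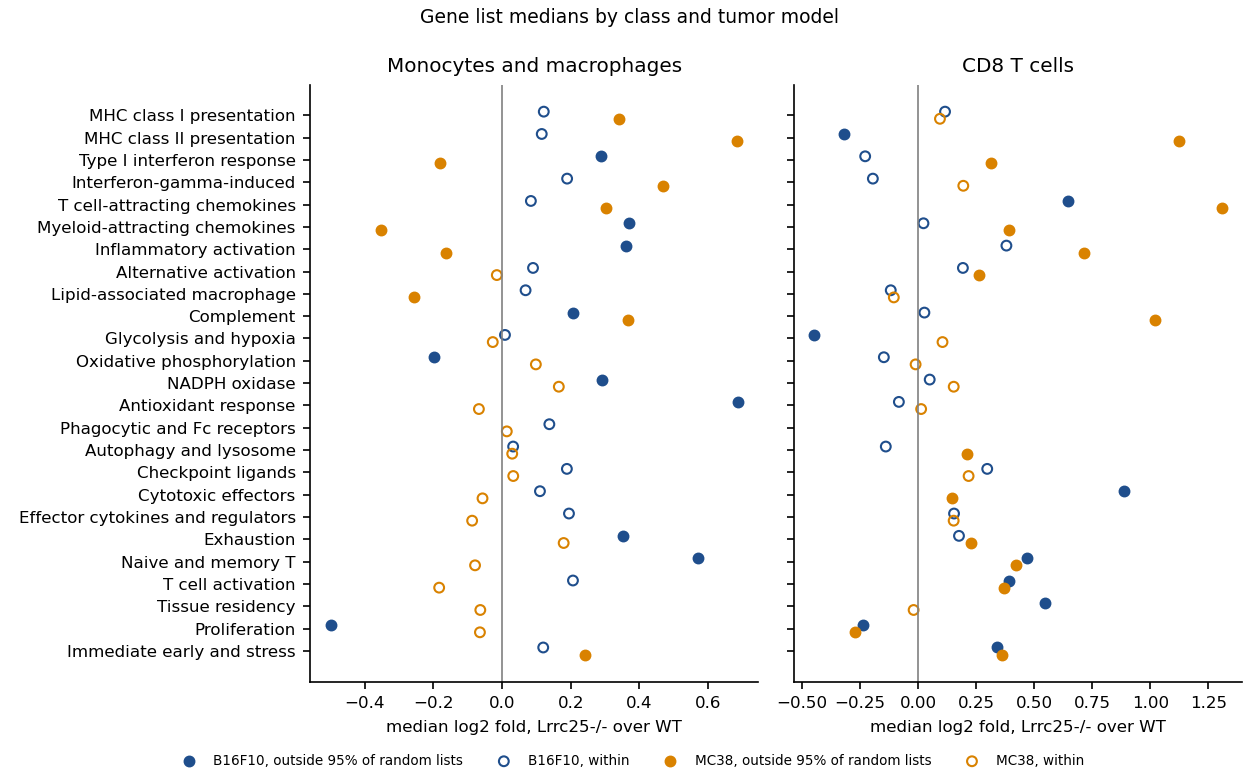
Median log2 fold (Lrrc25-/- over WT) of each gene list in monocytes and macrophages and in CD8 T cells, by tumor model; filled points lie outside the central 95% of random lists matched on expression, open points within it, and lists with fewer than 3 measured members are left out. In monocytes and macrophages, antioxidant genes had a median of 0.69 in B16F10 and -0.07 in MC38, and MHC class II genes 0.12 and 0.68.

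CD8 T cells of the Lrrc25-/- pools carried more RNA of the chemokines Ccl5 and Ccl4, which draw in T cells and myeloid cells, in both tumor models. Ccl5 went from 4019 to 7539 CPM in B16F10 (ratio 1.88, 1.81 to 1.94) and from 350 to 1013 CPM in MC38 (2.89, 2.70 to 3.10). Ccl4 went from 300 to 547 CPM (1.82, 1.61 to 2.07) and from 133 to 338 CPM (2.55, 2.28 to 2.86). The Ccl5 level in MC38 CD8 T cells was close to that of macrophages in the same library, at 87.4% of it in the WT pool and 91.6% in the Lrrc25-/- pool, whereas in B16F10 CD8 T cells it was 861% and 1497%. In MC38 the rise was not particular to CD8 T cells. Ccl5 went from 404 to 1051 CPM in NK cells and from 439 to 908 CPM in Treg cells there, and Ccl4 from 16.1 to 76.2 CPM and from 70.4 to 143 CPM. In B16F10, Ccl5 went from 6666 to 6094 CPM in NK cells and from 1439 to 2111 CPM in Treg cells. Also higher in CD8 T cells of both models were Zfp36 (log2 folds 0.79 and 0.79) and Tnfaip3 (0.69 and 0.73), which limit inflammatory signalling, Nfkbid, a nuclear regulator of NF-kappaB (0.73 and 0.74), and Lef1, a transcription factor of naive and memory T cells (0.87 and 0.71). Others were S1pr4 (0.73 and 0.74), Gramd3 (0.74 and 1.17), Ust (0.79 and 1.11) and Ccpg1 (1.82 and 0.87).

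Lower in both were Penk, the enkephalin precursor (822 to 271 CPM in B16F10, ratio 0.329, 0.299 to 0.363; ratio 0.631, 0.533 to 0.745, in MC38), the heat shock gene Hspa1a (log2 folds -0.69 and -0.93), the phosphatase Dusp14 (-1.94 and -0.68), Idi1 of sterol synthesis (-0.78 and -1.10), adenosine kinase Adk (-0.86 and -0.66), Rad51b (-1.07 and -0.79), Itgb3bp (-0.75 and -1.03) and Oxr1 (-0.73 and -0.70). Of 4638 genes measured in both models, 24 were higher in both (18.2 if independent), 8 lower in both (1.98) and 23 opposite (14.7).

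In the replicated test, edgeR called 2 of 10152 genes in CD8 T cells, both lower in the Lrrc25-/- pools, and 648 (6.38%) had an unadjusted p under 0.05. Galnt18, a glycosyltransferase gene, had a log2 fold of -1.77 (SE 0.281, adjusted p = 0.0131), but the difference rests on MC38 (212 to 57.0 CPM, lower in 1 of 2 models), since B16F10 gave 0 and 3 UMIs. Bcl2a1a, of the anti-apoptotic Bcl2a1 family, had a log2 fold of -2.70 (SE 0.459, adjusted p = 0.0191, lower in 2 of 2 models) and rests on B16F10 (96.8 to 6.70 CPM; 5.63 to 4.64 CPM in MC38). Reads are hard to divide among the near-identical Bcl2a1 genes, and Bcl2a1b and Bcl2a1d, looked up after this result, were not lower (log2 folds 0.06 and 0.49 in B16F10). DESeq2 called neither, nor did edgeR with the stricter cell filter (adjusted p 0.0597 and 0.167) or without a term for tumor model. DESeq2 called Ccl5 (log2 fold 1.20, adjusted p = 0.00597, higher in 2 of 2 models), which had an edgeR adjusted p of 0.158.

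In B16F10, CD8 T cells of the Lrrc25-/- pool had more RNA of granzymes and other cytotoxic effectors. Of 16 cytotoxic effector genes, 11 were higher and none lower, with a median log2 fold of 0.89, above all random lists. Gzme went from 6.24 to 115 CPM (ratio 18.5, 8.41 to 50.7), Gzmf from 15.6 to 80.7 CPM (5.17, 3.08 to 9.37) and Gzmd from 2.08 to 34.1 CPM (16.4, 4.43 to 137), although these rest on 6, 15 and 2 UMIs in the WT pool. Naive and memory genes had a median of 0.47 (above 99.7%; 4 of 10 higher), with Klf2, which holds T cells in a circulating state, at 166 and 418 CPM and S1pr1, the receptor for exit from tissue, at a log2 fold of 1.47. Tissue residency genes had a median of 0.55 (above 99.2%; 2 of 4 higher) and T cell activation genes one of 0.39 (above 99.6%; 1 of 10 higher). Exhaustion genes had a median of 0.18 (above 79.5%; 2 of 11 higher), with Tox at 64.5 and 111 CPM and Entpd1 at a log2 fold of 1.76. Glycolysis and hypoxia genes had a median of -0.45 (below all random lists; 2 of 16 lower, Pgk1 and Ndrg1) and proliferation genes one of -0.24 (above 0.51%). The size rule gave 732 genes higher and 193 lower of 5126 (617 and 263 with TMM scaling, 959 and 446 with means of per-cell CPM) from 200 WT and 751 Lrrc25-/- cells, and the median half-width of the counting intervals of the named genes was 0.45 on the log2 scale. The class held a different mix of lymphoid clusters in each pool: 1 cluster held 47.0% of WT and 26.4% of Lrrc25-/- cells, another 14.0% and 33.0%. The lowest genes were Plcb1 (1047 to 2.55 CPM), the chemokine Ccl17 (log2 fold -4.16), Bcl2a1a and the chemokine Ccl1 (871 to 95.7 CPM).

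In MC38, CD8 T cells of the Lrrc25-/- pool had higher chemokine RNA, while granzymes d, e and f, higher in B16F10, were not. The 4 measured T cell-attracting chemokines were all higher, with a median of 1.31 (above all random lists), against 0.65 (above 99.8%; 2 of 4) in B16F10. Cxcl9, on this list, stood at 969 and 1354 CPM in MC38 monocytes and macrophages, and macrophage RNA in the list median was not tested. Cytotoxic effectors had a median of 0.15 (above 99.0%; 4 of 16 higher), with Gzma at 22.2 and 146 CPM (ratio 6.57, 5.10 to 8.60) but Gzme at 543 and 404 CPM, Gzmd at 995 and 704 CPM and Gzmf at 3830 and 2968 CPM, none of the 3 past the size rule. Naive and memory genes had a median of 0.42 (above 99.99%; 3 of 7 higher), activation genes one of 0.37 (above all random lists; 1 of 10 higher, the costimulator Icos at a log2 fold of 0.90) and immediate early and stress genes one of 0.36 (above all random lists; 7 of 15 higher, 2 lower), against 0.34 (above 98.4%; 3 of 15 higher, 2 lower) in B16F10. Exhaustion genes had a median of 0.23 (above 99.1%; none higher, 1 lower), with Tox at 371 and 199 CPM. Proliferation genes had a median of -0.27 (above 0.06%). The size rule gave 154 genes higher and 242 lower of 6128 (225 and 169 with TMM scaling, 238 and 370 with means of per-cell CPM). Here too the mix of clusters differed, with 46.7% of WT and 21.1% of Lrrc25-/- cells in 1 lymphoid cluster and 25.8% and 61.9% in another. The highest after Gzma were the peptide transporter Slc15a2 (log2 fold 2.46), Ccl8 (1.85) and the CD30 ligand Tnfsf8 (11.9 to 41.5 CPM).

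Macrophage transcripts moved with part of this result. The macrophage markers summed to 199 and 404 CPM in MC38 CD8 T cells, against 400 and 408 CPM in B16F10. They move with the MHC class II list of MC38 CD8 T cells (median 1.12, above all random lists; 4 of 5 higher), its complement list (1.02, above all random lists; 3 of 3 higher), its inflammatory list (0.72, above all random lists; 5 of 8 higher) and with Ccl8. The macrophage marker C1qa stood at 1.65% and 2.66% of its macrophage level in these cells and Ccl8 at 1.37% and 2.44%, far below the shares given for Ccl5. In B16F10 these lists had medians of -0.32 (above 1.00%), 0.03 (above 44.8%) and 0.38 (above 96.2%; 1 of 8 higher, 1 lower). The remaining lists in CD8 T cells were effector cytokines and regulators (0.15 in B16F10, above 79.4%, and 0.15 in MC38, above 96.8%), type I interferon (-0.23, above 6.36%, and 0.31, above 99.1%), interferon-gamma-induced (-0.19, above 5.19%, and 0.19, above 96.7%), MHC class I (0.12, above 91.4%, and 0.09, above 92.6%), oxidative phosphorylation (-0.15, above 16%, and -0.01, above 30.2%), tissue residency in MC38 (-0.02, above 40.7%) and glycolysis in MC38 (0.11, above 95.1%). With TMM scaling the complement median in B16F10 and the oxidative phosphorylation and tissue residency medians in MC38 changed sign.

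**Figure D4:**
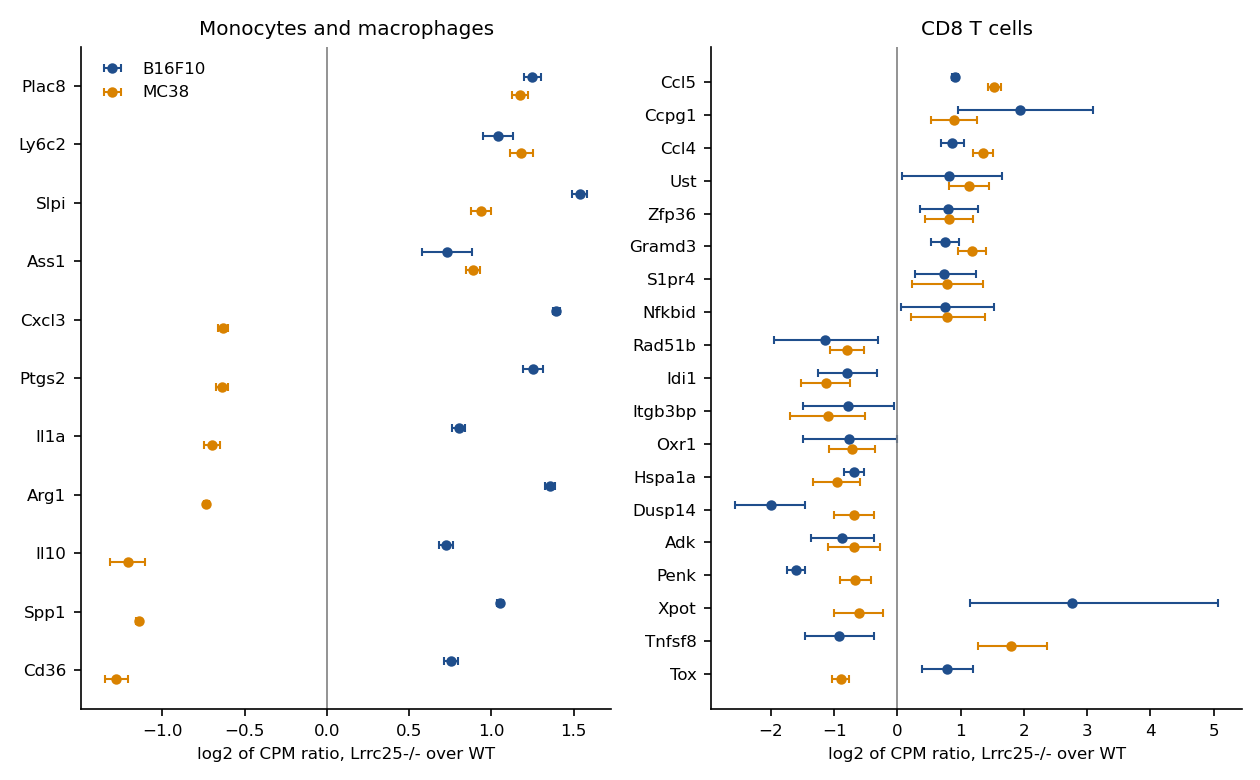
Log2 of the CPM ratio (Lrrc25-/- over WT, no pseudocount) of named genes in monocytes and macrophages and in CD8 T cells, by tumor model, with 95% intervals for counting error. In CD8 T cells Ccl5 lies at 0.91 in B16F10 and 1.53 in MC38, and in monocytes and macrophages Arg1 lies at 1.36 and -0.73.

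Other immune classes with at least 50 cells in every library were Treg cells, NK cells, neutrophils and migratory dendritic cells; fibroblasts also had that many but were not compared. Migratory dendritic cells, which carry antigen to T cells, had more RNA of Il12b, a subunit of interleukins 12 and 23, in both models (219 to 580 CPM, ratio 2.65, 2.09 to 3.41, in B16F10, and 439.5 to 1039 CPM, 2.36, 1.95 to 2.88, in MC38). Ass1 (166 to 316 CPM and 154 to 293 CPM) and the early response gene Ier3 (log2 folds 1.07 and 1.14) were higher too, and MHC class II genes had medians of 0.33 (above 99.8%) and 0.40 (above 99.99%). Macrophage marker RNA in these cells went from 648 to 434 CPM in B16F10 and from 716 to 1357 CPM in MC38, that of type 1 dendritic cells from 424 to 742 CPM and from 1149 to 1400 CPM, and that of type 2 dendritic cells from 654 to 940 CPM and from 1554 to 1508 CPM. Pdcd4 (-0.86 and -0.79), the nuclear body gene Sp100 (-1.39 and -0.75) and Idi1 (-0.59 and -1.82) were lower in both. Treg cells had more RNA of Irf4, a factor of effector Treg cells (ratios 2.62, 1.31 to 5.80, and 1.78, 1.15 to 2.83), of Nr4a3, induced by the T cell receptor (log2 folds 0.89 and 1.18), and of the macrophage-rich transcript Il1b (0.87 and 1.45). Lower in Treg cells were Lockd (-0.85 and -1.11), Ube2c of the cell cycle (-0.65 and -0.73) and Slc22a15 (-0.63 and -0.71). Markers of migratory dendritic cells in Treg cells went from 241 to 535 CPM in B16F10 and from 406 to 578 CPM in MC38. Macrophage marker RNA went from 337 to 305 CPM in B16F10 and from 198 to 478 CPM in MC38 in Treg cells, and from 659 to 471 CPM and from 186 to 383 CPM in NK cells.

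NK cells had more RNA of the NF-kappaB inhibitor Nfkbie (ratios 2.68, 1.30 to 6.22, and 2.14, 1.25 to 3.87), the RNA-decay enzyme Zc3h12a (log2 folds 1.22 and 1.00) and Slc16a6 (1.09 and 1.16), and less of Srm of polyamine synthesis (-0.80 and -0.91), Etfa (-0.78 and -0.65) and Cisd3 (-0.66 and -0.60). Markers of migratory dendritic cells in NK cells went from 135 to 276 CPM in B16F10 and from 129 to 203 CPM in MC38. Those of Treg cells went from 522 to 1037 CPM and from 1445 to 1226 CPM. Cytotoxic effector genes had a median of 0.38 in NK cells of B16F10 (above 99.99%; 5 of 15 higher) and of -0.12 in those of MC38 (above 5.85%; 2 of 14 higher, 2 lower). Granzyme B, named after its values were seen, went from 455 to 1277 CPM in B16F10 and from 2098 to 1106 CPM in MC38 (Gzmb). Among measured genes, neutrophils had more type I interferon response RNA in both models, with medians of 1.01 (above 99.7%; 6 of 6 higher) and 0.53 (above 98.9%; 4 of 12 higher). B16F10 neutrophils held 166817 UMIs in the WT and 743103 in the Lrrc25-/- pool. The summed-count minimum there favours genes high in the Lrrc25-/- pool, so the 6 of 6 may partly reflect which members were measured. Of all genes measured in neutrophils, 424 were higher and 288 lower of 1906 in B16F10, and 387 and 371 of 2131 in MC38. In MC38 neutrophils, markers of macrophages went from 1612 to 2663 CPM, of monocytes from 610 to 1455 CPM and of type 2 dendritic cells from 722 to 1636 CPM, while in B16F10 these were lower in the Lrrc25-/- pool. They had less Hmox1, which degrades heme (1433 to 666 CPM, ratio 0.465, 0.398 to 0.545, in B16F10, and 262 to 52.2 CPM, 0.199, 0.118 to 0.325, in MC38), less of the glycolytic regulator Pfkfb3 (log2 folds -0.99 and -1.28) and less Hspa1a (-1.20 and -0.81). The granule genes Camp, Ngp and Ltf passed the size rule as higher in both models but came from few cells. Camp had 534 UMIs from 6 of 442 cells in the Lrrc25-/- B16F10 pool and 700 UMIs from 7 of 259 cells in the Lrrc25-/- MC38 pool. Genes higher in both models in these 4 classes were fewer than or near the number given by independence in Treg cells (24, 31.3 if independent), neutrophils (48 and 74.5) and migratory dendritic cells (14 and 16.6), and above it in NK cells (39 and 25.3). Genes lower in both numbered 7 in Treg cells (3.92 if independent), 13 in neutrophils (25.2), 3 in migratory dendritic cells (3.69) and 4 in NK cells (2.72). Genes passing in opposite directions were above the number given by independence in all 4, with 49 in Treg cells (29.4 if independent), 124 in neutrophils (90.7), 35 in migratory dendritic cells (18.5) and 31 in NK cells (17.4).

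Some transcripts separated a library from the others in many cell classes at once, which sets them apart from responses of 1 cell type. Plcb1 (ENSMUSG00000051177, chromosome 2, 134786067 to 135475258, plus strand) measured 1047 CPM in CD8 T cells, 804 CPM in monocytes and macrophages, 1437 CPM in Treg cells, 1163 CPM in fibroblasts and 931 CPM in endothelial cells of the WT B16F10 pool, but 12.7 CPM in melanoma cells of the same library. Part of the cells carried it, with 1006 UMIs from 65 of 200 CD8 T cells and 75 UMIs from 22 of 89 neutrophils. The share was larger in other host classes, such as 2011 of 3811 macrophages, 56 of 90 Treg cells and 52 of 73 endothelial cells. CD8 T cells of the other pools measured 2.55, 2.98 and 2.58 CPM, but the 34 endothelial cells of the WT MC38 pool measured 1212 CPM. Kdm2b was lower in the Lrrc25-/- B16F10 monocytes and macrophages but not in its CD8 T cells (67.6 to 114 CPM). The mitochondrial transcript mt-Nd3 was 269 CPM in the WT and 73.6 CPM in the Lrrc25-/- MC38 monocytes and macrophages, against 7.74 and 17.9 CPM in B16F10. Gm42418, an rRNA-like transcript, was at 18500 and 25771 CPM in B16F10 and 39459 and 22666 CPM in MC38. These last genes fall outside the naming rule and are named after their values were seen.

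**Figure D5:**
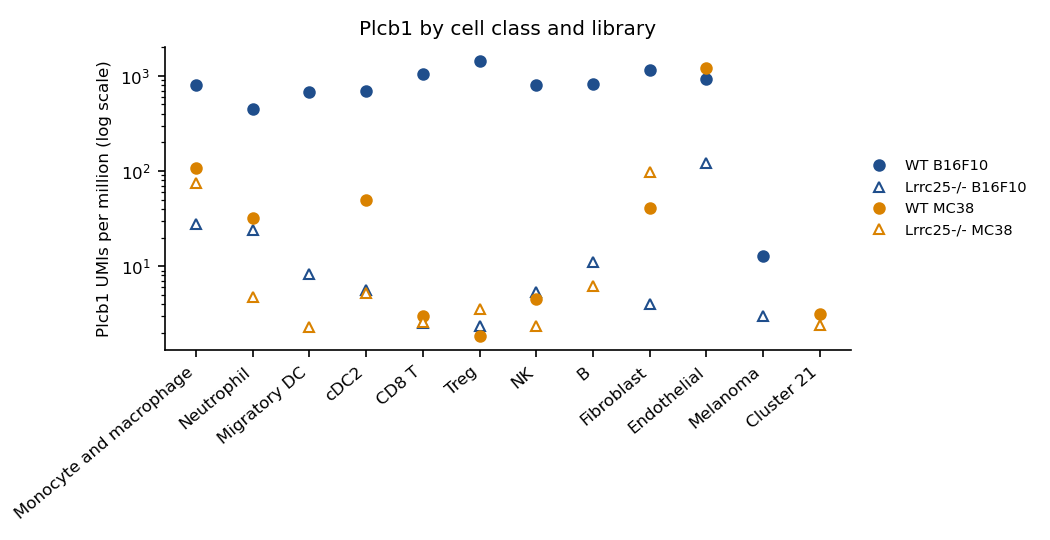
Plcb1 level (CPM, log axis) in 12 cell classes of the 4 pools, as filled circles (WT) and open triangles (Lrrc25-/-); points are missing where a class had no Plcb1 UMI or too few cells. CD8 T cells lie at 1047 CPM in the WT B16F10 pool and between 2.55 and 2.98 CPM in the other pools, and melanoma cells of the WT B16F10 pool at 12.7 CPM.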

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

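Of the tests here, those of Plcb1 against free RNA and against loss of Lrrc25, of dissociation stress, and of the Lrrc25 RNA left in Lrrc25-/- macrophages were chosen only after the result was seen, as were the split of the cluster and Gm42418 tests by tumor model and their intervals. The results given first stand out because the Lrrc25-/- pool lay above the WT pool in 1 tumor model and below it in the other. With 1 pool per genotype and model, the difference between the models was not tested, and it is given as MC38 minus B16F10 on the log2 scale. In monocytes and macrophages it was -0.47 for the median of the type I interferon response, -0.72 for myeloid-attracting chemokines and -0.52 for inflammatory activation. Among single genes of that class it was -2.02 for Cxcl3, -1.88 for Ptgs2, -1.49 for Il1a, -2.09 for Arg1, -1.89 for Il10, -2.20 for Spp1 and -2.01 for Cd36. In CD8 T cells it was 1.44 for the median of MHC class II presentation, beside macrophage markers at 199 and 404 CPM in the MC38 pools; with means of per-cell CPM, H2-Ab1 in CD8 T cells of B16F10 turned from -0.21 to 0.26. It was also -3.01 for Xpot, of which the WT B16F10 pool had 3 UMIs, 2.62 for Tnfsf8 and -1.67 for Tox in CD8 T cells.

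For 15 of the 16 genes with opposite folds in monocytes and macrophages, a standard mix of clusters left 0.953 (0.864 to 1.20) of the fold in the median gene in MC38, which argues against a different mix as the whole cause there, although the clusters were built partly on these genes. In B16F10 it left 0.771 (0.569 to 0.997), so a shift among clusters may account for part of the folds. Comparing cells of a like share of Gm42418, an rRNA-like transcript, left 0.953 (0.799 to 1.05) in B16F10 and 1.03 (0.911 to 1.22) in MC38. For Cdk8 it left 0.430 and 0.0438, and for Cmss1 0.452 and 0.306. The median gene thus kept its fold, while Cdk8 and Cmss1 lost most of theirs. Grouping cells by this share cannot remove a difference in preparation between whole libraries, so the comparison does not decide on such a difference. The bracketed range beside each of these medians comes from the ranks of the 15 gene values. Genes of the same pair of libraries are not independent replicates, so the range covers neither counting error nor the spread between pools. Immediate early and stress genes had medians of 0.12 and 0.24, but in MC38 1 of 14 was higher and 3 lower, so stress of dissociation cannot be told apart from the other sources. A response to loss of Lrrc25 that depends on the tumor, on the sex of the hosts or on the day of collection stays open and was not tested, and the spread between pools is unknown.

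Plcb1 was high in host cells of the WT B16F10 pool and not in its melanoma cells, and 65 of its 200 CD8 T cells held all of that class's UMIs, so the class level is a mean over unlike cells of 3 pooled mice. Other classes had larger shares of cells with a UMI, such as 56 of 90 Treg cells. The share in CD8 T cells thus does not show how many of the mice carried it. Melanoma cells held 0.0121 of the level in CD8 T cells, which argues against free RNA, and CD8 T cells of the WT MC38 pool measured 2.98 CPM, which argues against a gene that loss of Lrrc25 turns off in T cells of any host. A chromosome segment that differs between the hosts of the pools remains a candidate explanation: 2 of 17 measured genes within 5 Mb passed the size rule in monocytes and macrophages, 2.36 times the share of all measured genes (4.98%). That is too few genes to decide.

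A low level of Lrrc25 remained in macrophages of the Lrrc25-/- pools. CD8 T cells of these pools had no Lrrc25 UMI, with upper limits of 1.18 CPM in B16F10 and 0.952 CPM in MC38, below the lower bounds in monocytes and macrophages (4.06 and 1.77 CPM), which argues against free RNA. The UMIs were spread thinly, over 198 cells in B16F10 and 115 in MC38, where draws of WT cells holding as many UMIs gave 96 (83 to 109) and 83 (73 to 92), which argues against WT cells mixed in as the whole cause. Plcb1 in monocytes and macrophages also kept 28.0 of 804 CPM in the Lrrc25-/- B16F10 pool, a share like that of Lrrc25. But these cells held 107 and 74.9 CPM in MC38. The shares were alike in B16F10 macrophages (Plcb1 19.4 of 801 CPM, Lrrc25 4.74 of 158 CPM). In B16F10 monocytes they were not (Plcb1 159 of 892 CPM, Lrrc25 3.59 of 197 CPM). Transcripts from the targeted allele could give the 210 Lrrc25 UMIs of the Lrrc25-/- B16F10 pool and the 115 UMIs in MC38. The matrices hold no read positions, so this cannot be told apart from other sources in the macrophages themselves.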

How the results depend on the processing

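Of the tests here, macrophages alone was the only alternative chosen after the data had been seen, and the cause of the changes below was not tested except where given. The fit across models paired the pools by tumor model through its second term. No further pairing was possible because the labels number no replicates and each genotype and model has 1 pool. Without any 1 library the fit across models has no residual degrees of freedom, so that alternative gives no test. For shares, named genes and Lrrc25, a value that moved lies outside the 95% counting interval of the reported value. The Lrrc25 fold stayed inside it, at 34.4 and 34.0 in B16F10 (reported 34.1) and 41.9 and 42.1 in MC38 (reported 42.4). None of 396 alternative list medians moved by more than the half-width of its range in random lists, and of 2657 named-gene values 307 moved. The sign changed in 14 of these medians, 0 of them outside the central 95% of random lists, and in 28 of these values, 0 of them past the size rule. Of 152 shares, 128 stayed inside their interval and 22 moved. The CD8 T share ratio in B16F10 was 3.79 at Leiden resolution 2. With each cell named by its own marker score, ratios were 1.59 and 1.55 for CD8 T cells in B16F10 and MC38, 1.36 and 1.58 for all T cells, and 0.981 for monocytes and macrophages in MC38, while cDC2 in B16F10 (0.912) and pDC in MC38 (0.602) reversed. With no CPM minimum, where more genes are measured, the size rule gave 473 higher and 185 lower for monocytes and macrophages in B16F10, 134 and 505 in MC38, and 284 and 416 for CD8 T cells in MC38. With means of per-cell CPM it gave 287 higher for monocytes and macrophages in B16F10, 446 lower for CD8 T cells in B16F10 and 238 higher and 370 lower for those in MC38, and with TMM scaling 80 higher for monocytes and macrophages in MC38. Across models, the genes called for monocytes and macrophages were 2 with RLE size factors, 12 with DESeq2, 103 with no filter on low counts, 0 with no tumor model term (edgeR, 7 at an unadjusted p under 0.05) and 2 with doublets kept. For CD8 T cells they were 27, 1, 39, 0 (edgeR, 6 unadjusted) and 14, and 0 with the stricter cell filter (edgeR, 625 unadjusted). The Lrrc25 call was lost only without the tumor model term, and those of Galnt18 and Bcl2a1a also under DESeq2 and the stricter filter. Depth limits the small classes: the median counting half-width (log2) of named genes in B16F10 was 0.06 for monocytes and macrophages, 0.45 for CD8 T cells and 0.89 for NK cells.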

Other observations

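The tumor-cell comparisons here were not among the planned tests and were chosen after the data had been seen. Melanoma cells of the Lrrc25-/- B16F10 pool differed from those of the WT pool by at least 1.5-fold in 106 of 4582 genes, 94 higher and 12 lower, and their median mitochondrial share of UMIs was 0.912% against 0.270%. MHC class II genes had a median log2 fold of 0.65 (above all random lists, 3 of 5 higher), and MHC class I genes one of 0.23 (above 99.6%, none of 8 past the size rule). The macrophage marker C1qa was at 30.9 and 31.3 CPM in these cells, while cDC2, cDC1 and migratory DC were 2.86, 1.91 and 2.06 times as large a share of all cells in the Lrrc25-/- pool as in the WT pool. The highest gene, Cxcl3 (9.10 to 26.4 CPM), was at 714 and 1879 CPM in monocytes and macrophages of these libraries. Its log2 fold was 1.44 in melanoma cells and 1.40 in monocytes and macrophages. C1qa stood at 1.15% and 1.26% of its macrophage level in melanoma cells, and Cxcl3 was likewise far below its own. The Cxcl3 difference therefore cannot be told apart from RNA of macrophages. RNA of other cells in the class II values was not tested. Higher genes included the receptor tyrosine kinase Met (84.1 to 186 CPM), the metabolic coactivator Ppargc1a (112 to 262 CPM), Bnc2 (17.5 to 43.1 CPM) and the lipase gene Mgll (233 to 483 CPM). The stress-linked Gdf15 (170 to 102 CPM) and the cell cycle inhibitor Cdkn1a (253 to 153 CPM) were lower, and proliferation genes had a median of -0.17 (above 0.02%).

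In MC38, the cluster led by Sox9, Tnnt2 and Crabp2 had no listed marker type, and the labels do not name it. Xist measured 12.2 and 21.3 CPM in its WT-pool and Lrrc25-/--pool cells. Monocytes and macrophages of the same pools had 651 and 665 CPM, which argues against host cells as the bulk of this cluster. In cells of this cluster from the Lrrc25-/- pool, interferon-gamma-induced genes had a median log2 fold of 0.63 (above all random lists, 8 of 12 higher). Among them were the transcription factor Irf1 at 272 and 440 CPM, the GTPase Gbp2 at 271 and 422 CPM and the chemokine Cxcl10 at 317 and 484 CPM. MHC class I genes had a median of 0.43 (above all random lists, 2 of 14 higher), with the immunoproteasome subunits Psmb9 (128 to 217 CPM) and Psmb8 (log2 fold 0.62) and H2-K1 (1672 to 2160 CPM). Irf1 and Cxcl10 were above their levels in monocytes and macrophages of the same libraries (77.3 and 108 CPM, and 216 and 235 CPM). Cxcl9, of the same list and higher too in this cluster (21.2 to 47.0 CPM), was far below its level there (969 and 1354 CPM). Its rise cannot be told apart from RNA of macrophages. MHC class II genes had a median of 1.17 (7 of 7 higher), but C1qa also went from 31.1 to 61.5 CPM in these cells. The growth factor gene Csf2 went from 23.1 to 48.4 CPM, and the axon guidance gene Slit2 from 134 to 75.0 CPM.

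Ddx3y, on the Y chromosome, measured 25.5 and 29.5 CPM in monocytes and macrophages of the B16F10 pools and 0.0666 and 0 CPM in those of the MC38 pools. Erythroid marker RNA in B16F10 monocytes and macrophages was 85.5 CPM in the WT and 18.2 CPM in the Lrrc25-/- pool.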
